A study of Mus musculus with 12 samples.

How the data were processed

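The series holds 12 RNA libraries of mouse mammary gland, 4 each of the groups Control, Met and Met-Met, as the labels give them. Per the labels, RNA was extracted with TRIzol and libraries followed a standard Illumina preparation. The deposited values are FPKM that the authors calculated per transcript, in 1 table per library for protein-coding transcripts (55869 transcripts of 21956 genes) and in 1 table each for annotated lncRNAs (1822 transcripts, 1533 genes) and assembled lncRNAs without annotation (6871 transcripts, 6405 genes). The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.8, StringTie 1.3.1 and the builds GRCm38 and mm9, without saying which served which step. No coordinates are in the tables. Read numbers are not given and could not be recovered from the values, so the depth per library is unknown and so is the precision of low values. Gene identifiers were matched to reference names for 21816 genes.

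FPKM were summed per gene. The 11809 genes with a mean of at least 1 FPKM were tested. Each library was divided by its median ratio to the mean of all libraries (divisors 0.832 to 1.22), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 3 group means over all 12 libraries and moderated variances with an intensity trend. A gene was called when its p, adjusted by Benjamini-Hochberg over the genes of a comparison, was under 0.05. The comparisons were Met against Control, Met-Met against Control and Met-Met against Met. For lncRNAs the minimum mean was 0.5 and the pseudocount 0.5. Of the tested genes, 51 were listed at 0 in at least 1 library. On simulated data (10 runs, 200 changed genes each), the fit recovered 97.1% of genes changed by −2 log2 units, 83.6% at 1 and 41.5% at 0.5. There 4.99% of its calls were unchanged genes, a rate not measured in these libraries.

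Gene lists (34, of which 15 hold cell type markers) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over the lists. The rotation test fry was run beside them. List means and shares per library were compared by exact two-sided permutation over the 70 arrangements of 4 against 4 libraries. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.

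Genes named in the text follow a fixed rule. Per comparison it takes the 10 highest and the 10 lowest log2 fold changes among called genes whose groups do not overlap and that carry a proper symbol. From each list that is called or holds a called gene it adds up to 4 members with the smallest p, and it always adds Csn2, Wap, Lalba, Elf5, Stat5a, Prlr, Mat2a, Asns, Slc15a2, Mtor, Mki67, Adipoq and Krt14. For lncRNAs it takes the 3 highest and 3 lowest called. Some genes that the rule names are not reported here. Comparisons, thresholds, lists, this rule and most alternatives were chosen before the data were examined.

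Those alternatives were FPKM as deposited or quantile normalization, pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, the 8 libraries of a comparison alone, library quality weights, the replicate number as a block, no intensity trend, the adipocyte or B cell marker mean as a covariate, 1 transcript per gene, and leaving out each library in turn. Chosen after the data were seen were the fits without the 3 libraries with high Gm26917, without the 6 libraries with lymphocyte markers and without genes listed at 0, an indicator of high Gm26917, both marker means together, the B cell covariate for lncRNAs, and the counts of genes at 1 scaled FPKM or without the 6 libraries.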

Results

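RNA was sequenced from the 4th inguinal mammary gland of ICR mice, an outbred stock, at day 17 of pregnancy, when the epithelium prepares to make milk. Mice of the Met group ate food lacking methionine and were given methionine by intraperitoneal injection, at 35% of what the control diet holds. In the Met-Met group 25% of that injected methionine was methionyl-methionine, a peptide of 2 joined methionine residues. The labels name a control diet and say no more of the Control group. Each group had 4 libraries, 12 in all. Comparisons with Control cannot separate methionine amount from diet or injection. Met-Met against Met asks what the dipeptide alters. The labels state 4 per group without saying that each library is a separate mouse, so the p-values measure only the spread between these samples, which may be technical. Levels are scaled FPKM, given as mean ± SD with n = 4 per group. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels.

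Some libraries differed in ways that the groups do not describe. The mean of the B cell markers was 2.53 to 3.01 log2 units in Control 1, 2 and 3, 1.34 to 1.39 in Met 4, Met-Met 1 and Met-Met 3, and 0.108 to 0.315 in the other 6 libraries. T cell markers followed the same 6 libraries. Skeletal muscle markers averaged 4.76 in Met 2 and at most 0.802 elsewhere, and skin keratinocyte markers were also highest there, at 3.37. The noncoding gene Gm26917 was listed at 9305, 9013 and 9230 FPKM in Met 3, Met 4 and Met-Met 2, against 72.3 to 99.2 in the other 9 libraries. Those 3 libraries are too few for a comparison and hold no Control, so values within the remaining 9 (4 Control, 2 Met and 3 Met-Met) are given beside those of all 12.

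Fewer genes reached 1 FPKM as deposited in Met (11237 ± 209) and in Met-Met (11489 ± 141) than in Control (12028 ± 268). Both differences gave p = 0.0286 in an exact two-sided permutation test, the smallest that 4 against 4 libraries allow (adjusted p = 0.0429 over 3 comparisons), while Met-Met and Met gave an exact p of 0.143. In the 9 libraries the differences from Control were −806 genes for Met (exact permutation p = 0.0667, the smallest possible there) and −486 genes for Met-Met (exact permutation p = 0.0571). The count followed the divisor used for scaling (Spearman correlation 0.923 over 12 libraries). With scaled FPKM the differences were −464 for Met and −419 for Met-Met (exact permutation p = 0.0286 for each). Within each group the libraries with lymphocyte markers had the most genes at 1 FPKM as deposited, and without those 6 libraries the differences were −558 for Met and −333 for Met-Met, against Control 4 alone and so not tested.

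In Met glands, genes of the amino acid response were higher than in Control, and genes of adipocytes, matrix and dividing cells were lower. With an estimated correlation these lists gave adjusted p = 0.371, 0.682, 0.371 and 0.581. Asns, which makes asparagine and is a target of the transcription factor ATF4, stood at 79.9 ± 9.88 in Met and 26.6 ± 4.53 in Control (log2 fold change 1.56, adjusted p = 5.95e-05). Odc1, the first enzyme of polyamine synthesis, was at 186 ± 22.9 against 48.4 ± 6.76 (1.92). Lep, the adipocyte hormone leptin, was at 1.39 ± 0.565 against 50.9 ± 9.73 (−4.45), and Col1a2, a chain of type I collagen, at 77.6 ± 9.52 against 205 ± 11.4 (−1.40). The major milk protein gene Csn2 (beta-casein) was at 73662 ± 14483 against 37952 ± 11647 (0.99, adjusted p = 0.00978).

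Limma called 3346 of 11809 genes between Met and Control, 1570 higher and 1776 lower in Met, of which 130 and 318 differed at least 2-fold. With FPKM as deposited the median of all genes shifted by −0.25 on the log2 scale and 4651 genes were called, 352 higher and 4299 lower, with 184 of the 3346 turning sign. All changes are therefore relative to the scaled median of the libraries. In the 9 libraries 2338 genes were called, and without Control 1 or Control 2 the counts were 2126 and 2144. Restricting the test to genes with a mean of at least 5 FPKM left 2192 calls. The adipocyte marker mean, 6.39 to 6.67 in Control and 5.51 to 5.78 in Met, left 394 calls as a covariate, the B cell marker mean 1478 and both together 133. Without the 6 libraries that hold lymphocyte markers, which leaves 1 Control library assumed to vary like the others, 8 genes were called, 6 of them among the 3346. Of the named calls, 66 of 69 were lost there, 35 with the adipocyte covariate, 49 with both, and 13 of 77 with the B cell covariate.

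Among the genes with separated groups, the 10 highest fold changes in Met belonged to the basal keratin Krt15 (2.6), the peptide hormone Adm2 (2.53), the collectin Sftpd (2.45), the transcription factor Tfcp2l1 (2.44), the antimicrobial peptide Defb1 (2.39), the calcium pump Atp2b2 (2.39), the ATF4 targets Trib3 (2.36) and Mthfd2 (2.12), the glutathione-degrading enzyme Chac1 (2.02) and the receptor partner Ramp3 (1.98). Chac1 spread widely in Met (20.2 ± 23.6 against 2.89 ± 1.83). Its call was lost without Control 1 (adjusted p = 0.0803), without Control 2 (0.0792) and in the 9 libraries (0.108), range 0.00764 to 0.262 over its alternatives. The 10 lowest were Lep (−4.45), the natriuretic peptide receptor Npr3 (−3.57), Sncg (−3.53), the imprinted genes Nnat (−3.48) and Mest (−2.73), the lipid droplet gene Plin4 (−2.71), Tmem45b (−2.37), Glb1l2 (−2.27) and the globins Hbb-bt (−2.28) and Hba-a2 (−2.25). Tmem45b was at 10.9 to 15.1 in the Control libraries, at 2.6, 2.28 and 3.00 in Met 1, 2 and 3, and listed at 0 in Met 4.

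The ATF4 target list rose as a group in Met, with a median log2 fold change of 1.10 (1.03 in 9 libraries; camera adjusted p = 1.39e-12, or 0.371 with an estimated correlation). Of 27 members, 20 rose and 0 fell (21 and 0 over the list alone), where the second counts adjust p over the list's members only. Atf5 was at 93.0 ± 27.4 against 25.8 ± 4.06, beside the mitochondrial folate enzyme Aldh1l2 (1.63) and the transporter subunit Slc3a2 (1.3). Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose as a list with a median of 0.47 (0.42 in 9 libraries; adjusted p = 6.37e-05, or 0.512 with an estimated correlation). Of 20 members, 10 rose and 0 fell (12 and 0 over the list alone), with examples Nars (0.93), Mars (0.83) and Gars (0.95). The list of methionine cycle, transsulfuration and polyamine genes was called higher (median 0.21, 0.19 in 9 libraries, adjusted p = 0.0387, or 0.371 with an estimated correlation), but its median is −0.07 with FPKM as deposited. Of 24 members, 6 rose and 2 fell (6 and 2 over the list alone). The members that rose include Odc1, Gnmt (1.34), which uses S-adenosylmethionine to methylate glycine, and Cth (1.89), which makes cysteine, while Nnmt, another user of S-adenosylmethionine, fell (−1.53). The call was lost in the 9 libraries (adjusted p = 0.0772), without Control 4 (0.0534) and without Met 4 (0.0817), range 0.00133 to 0.0817.

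The list of PI3K, AKT and mTORC1 genes was called higher in Met at the edge of the threshold (median 0.12, 0.11 in 9 libraries, adjusted p = 0.0496, or 0.512 with an estimated correlation), and its median turns to −0.17 with FPKM as deposited. Of 35 members, 8 rose and 3 fell (8 and 3 over the list alone), with Rheb (0.57), the activator of mTORC1, and Eif4ebp1 (1.08), a brake on translation, among those that rose. The adjusted p ranged from 0.00833 to 0.244 over alternatives. It was above 0.05 without Control 2 (0.0753), Control 4 (0.0534), Met 2 (0.174), Met-Met 2 (0.0509), Met-Met 3 (0.0537) or Met-Met 4 (0.0516), with either other scaling (0.244 as deposited, 0.194 quantile-normalized), with the adipocyte or B cell covariate (0.0811 and 0.0850), with both (0.139) and without the 6 lymphocyte-marked libraries (0.0519). Amino acid transporters were not called (median 0.11, and −0.10 as deposited, adjusted p = 0.322), although 7 members rose and 4 fell, against 7 and 5 over the list alone. Peptide transport and hydrolysis genes were not called either (adjusted p = 0.904), with a median of −0.01, a mean of −0.03 and a test in the positive direction.

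Ribosomal protein genes were higher in Met as a group, with a median of 0.46 (0.61 in 9 libraries), 0.16 as deposited and 0.12 quantile-normalized (adjusted p = 5.09e-17, or 0.475 with an estimated correlation). Of 77 members, 56 rose and 0 fell (62 and 0 over the list alone). Their share of the summed FPKM did not show this, at 7.28 ± 0.778% in Met and 7.39 ± 0.922% in Control (exact permutation p = 0.83). Rpl23 was at 440.0 ± 36.4 against 294 ± 13.7 (0.58) beside Rps16 (0.54). The Rps16 call was lost as deposited (0.105) and quantile-normalized (0.0864), range 7.32e-04 to 0.177. Rpl12 was at 322 to 564 in the 3 libraries with high Gm26917 and at 5.38 to 10.1 in the others. Oxidative phosphorylation genes also rose, with a median of 0.31 (0.37 in 9 libraries), 0.01 as deposited and 0.13 quantile-normalized (adjusted p = 2.40e-13, or 0.503 with an estimated correlation). Of 76 members, 39 rose and 0 fell (48 and 0 over the list alone), with the complex I subunits Ndufa2 (0.58) and Ndufv2 (0.52). Ndufv2 was not called as deposited (adjusted p = 0.143, range 5.36e-04 to 0.198). Whether a trend of short mRNAs raised both lists was not tested. ER chaperone and unfolded protein response genes rose too, with a median of 0.56 (0.53 in 9 libraries; adjusted p = 6.37e-05, or 0.512 with an estimated correlation). Of 18 members, 11 rose and 0 fell (12 and 0 over the list alone). They include Sdf2l1 (1.72), the disulfide isomerase Pdia6 (0.90) and Hyou1 (1.14).

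Fibroblast and matrix markers were lower in Met, with a median of −1.22 (−1.08 in 9 libraries; adjusted p = 4.42e-09, or 0.371 with an estimated correlation). Of 14 members, 0 rose and 11 fell (0 and 11 over the list alone). The microfibril gene Fbn1 (−1.52) and Sparc (−1.25) fell. Myoepithelial markers fell as a list (median −0.46, −0.46 in 9 libraries, adjusted p = 0.00107, or 0.371 with an estimated correlation), with the contractile genes Acta2 (−1.11) and Tagln (−0.67). Of 12 members, 1 rose and 7 fell (1 and 9 over the list alone). Cell division genes fell too, with a median of −0.88 (−0.83 in 9 libraries; adjusted p = 2.56e-08, or 0.581 with an estimated correlation). Of 30 members, 0 rose and 20 fell (0 and 20 over the list alone), as in Cenpa (−1.54), Ccnb2 (−1.52) and Ccnb1 (−1.63). Erythrocyte genes fell as a list with a median of −2.24 (−2.27 in 9 libraries; adjusted p = 0.00138, or 0.512 with an estimated correlation). Of 5 members, 0 rose and 5 fell (0 and 5 over the list alone), for example Hba-a1 (−2.24) and Alas2 (−1.08), the first enzyme of haem synthesis in red cells. Hba-a1 was not called in the 9 libraries (0.0576, range 0.00182 to 0.152). Macrophage markers fell as a list, with a median of −0.46 (−0.48 in 9 libraries; adjusted p = 0.00150, or 0.475 with an estimated correlation). Of 11 members, 1 rose and 8 fell (1 and 9 over the list alone), among them Csf1r (−0.81) and Cd68 (−0.57).

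Adipocyte markers were lower in Met, with a median of −0.84 (−0.93 in 9 libraries; adjusted p = 0.00307, or 0.682 with an estimated correlation). Of 15 members, 1 rose and 9 fell (1 and 9 over the list alone). The glycerol channel Aqp7 (−1.29) fell, while the complement factor adipsin, Cfd (1.3), rose. That call was lost with FPKM as deposited (adjusted p = 0.0645) and, by construction, with the list's own mean as a covariate (0.458, or 0.453 with the B cell mean added), range 7.96e-05 to 0.458. B cell and T cell markers were called lower in Met. The B cell median was −1.64 (−1.90 in 9 libraries; adjusted p = 0.00150, or 0.682 with an estimated correlation). Of 10 members, 0 rose and 5 fell (0 and 10 over the list alone). The T cell median was −1.60 (−2.06 in 9 libraries; adjusted p = 0.00108, or 0.682 with an estimated correlation). Of 12 members, 0 rose and 4 fell (0 and 12 over the list alone). Cd22 was at 0.349 ± 0.413 against 4.43 ± 3.01, and Fcer2a at 5.39, 6.82 and 6.42 in Control 1 to 3, listed at 0 in Control 4, and at 0.0599 to 0.677 in the Met libraries. Without the 6 libraries with these markers, chosen by the B cell mean, the B cell call is lost by construction, as with that mean as a covariate. Adjusted p without them was 0.502 for B cells and 0.859 for T cells, with the B cell covariate 0.978 and 0.879, with both 0.918 and 0.798, and as deposited it was 0.110 for each, within ranges of 6.98e-08 to 0.978 and 5.86e-08 to 0.879. Neither Cd22 nor Fcer2a was called without Control 1 (0.0873 and 0.0839), Control 2 (0.0960 and 0.0890), Control 3 (0.0872 and 0.0788), Met 1 (0.0742 and 0.0669), Met 2 (0.0675 and 0.0606) or Met 3 (0.0719 and 0.0653), nor in the 9 libraries (0.0883 and 0.0924).

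Per library, the marker means of myoepithelial cells, adipocytes, fibroblasts, endothelium, macrophages and erythrocytes lay lower in each Met library than in each Control library, and that of brown adipocytes higher (exact permutation p = 0.0286, the smallest possible, and adjusted p = 0.0612 over 15 marker lists). The B cell marker mean gave an exact permutation p of 0.143. The lists of endothelium (median −0.18, adjusted p = 0.0947), brown adipocytes (0.48, 0.730), luminal epithelium (−0.13, 0.730, but called lower quantile-normalized, 0.0287), Schwann cells (−0.17, 0.466), skin keratinocytes (0.67, 0.704) and plasma cells (0.06, and −0.20 as deposited, 0.730) were not called. Hormone-sensing luminal markers were not called (median −0.06, mean 0.03, median 0.11 quantile-normalized, adjusted p = 0.931). Skeletal muscle genes had a median of 1.16 (adjusted p = 0.102), and in the 9 libraries, where Met 2 is 1 of 2 Met libraries, 2.29 (adjusted p = 0.00420). They were called without Met 1 (0.0247), Met 3 (0.0322) or Met 4 (0.0456).

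Milk protein genes rose as a list in Met, with a median of 0.64 (0.81 in 9 libraries), 0.34 as deposited and 0.07 quantile-normalized (adjusted p = 0.00359, or 0.697 with an estimated correlation). Of 19 members, 10 rose and 1 fell (11 and 2 over the list alone). Csn1s2a, an alpha-casein, was at 82742 ± 12936 against 42366 ± 12042, beside Lao1 (0.96), the amino acid oxidase of milk, and Xdh (0.86), of the fat globule membrane. In the opposite direction Lalba, the alpha-lactalbumin of lactose synthesis, fell from 308 ± 128 to 123 ± 90.4 (−1.50, adjusted p = 0.0351). The list call was lost after quantile normalization (adjusted p = 0.869), which sets the highest genes of each library equal and left Csn2 and Csn1s2a at a fold change of 0, with the B cell covariate (0.120) and with both covariates (0.331), range 1.79e-07 to 0.869. Milk protein genes took 47.9 ± 3.41% of the summed FPKM in Met and 36.9 ± 7.21% in Control (exact permutation p = 0.0571, adjusted p = 0.171 over 3 comparisons), and the difference of 11 percentage points was 10.4 in the 9 libraries (exact permutation p = 0.2, smallest possible 0.0667). Without Control 3 the difference was 13.6 percentage points (exact permutation p = 0.0286). Wap, the whey acidic protein, was at 46723 ± 13255 against 21195 ± 10916 (1.25, adjusted p = 0.0310).

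Wap was not called without Control 1 (0.0861), Control 2 (0.0813), Met 2 (0.0709) or Met 3 (0.0819), and Lalba without Control 2 (0.0510), Control 3 (0.0812), Control 4 (0.0830), Met 1 (0.0918) or Met 4 (0.0777). In the 9 libraries Csn2 (0.0515), Wap (0.110) and Xdh (0.0599, and 0.0724 after quantile normalization) were not called. Over all alternatives adjusted p ran from 0.00245 to 1.00 for Csn2, 0.00682 to 0.654 for Wap, 0.00174 to 0.534 for Xdh and 0.00551 to 0.333 for Lalba.

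Milk fat genes were not called as a list (median 0.07, −0.24 as deposited and −0.14 quantile-normalized, adjusted p = 0.208), with Elovl5 (0.70) and Lpin1 (1.10) among 4 that rose and Scd1, the stearoyl-CoA desaturase, the 1 that fell (−1.12). The counts were also 4 and 1 over the list alone. Lactose genes had a median of 0.12, a mean of −0.04 and a median of −0.18 as deposited (adjusted p = 0.904). Prolactin and STAT5 genes had a median of −0.11, a mean of 0.04 and a test in the positive direction (adjusted p = 0.787), and Cish, a feedback inhibitor induced by STAT5, rose (1.06). Cholesterol synthesis genes were not called (median 0.05, −0.24 as deposited, adjusted p = 0.918). Nor were those of interferon response (−0.29, 0.704), DNA and RNA methylation (0.03, −0.25 as deposited, 0.731), immediate-early and heat-shock response (−0.12, 0.628) and glutathione defence (median 0.06, mean −0.05, −0.25 as deposited and −0.14 quantile-normalized, 0.833).

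Of the genes followed throughout, Mki67, a proliferation marker, fell (−0.96, adjusted p = 0.00451), Adipoq, the adipocyte hormone adiponectin, fell (−1.08, 0.0233), and the prolactin receptor Prlr rose (0.36, 0.0318). The Adipoq call was lost without Control 1 (0.0629), Control 2 (0.0562), Met 1 (0.0620) or Met 2 (0.0509), range 0.00114 to 0.653. The Prlr call was lost as deposited (0.607), quantile-normalized (0.0724), in the 9 libraries (0.132) and without Control 1 (0.0920), Control 2 (0.0862), Met 1 (0.0600), Met 2 (0.0548) or Met 3 (0.0753), range 0.00628 to 0.918. Mat2a, which makes S-adenosylmethionine, was at 55.1 ± 36.6 against 24.7 ± 2.68 and was not called (0.88, adjusted p = 0.108), but was without Met 2 (1.27, adjusted p = 0.0118) and with library quality weights (0.0314). Without that library the epithelial transcription factor Elf5 (0.20, adjusted p = 0.196) and Krt14 (−0.30, 0.0520) were also called, at 0.31 (0.0187) and −0.36 (0.0346), Krt14 also with either other scaling (0.00191 as deposited, 0.0110 quantile-normalized) and with weights (0.0402), and Elf5 turns to −0.11 as deposited and −0.12 quantile-normalized. Stat5a (−0.11, 0.474), Mtor (−0.03, 0.786) and the peptide transporter Slc15a2 (0.01, 0.980, and −0.28 as deposited) were not called, but as deposited Stat5a (−0.42, 0.00840) and Mtor (−0.31, 0.0107) were called lower.

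**Figure D1:**
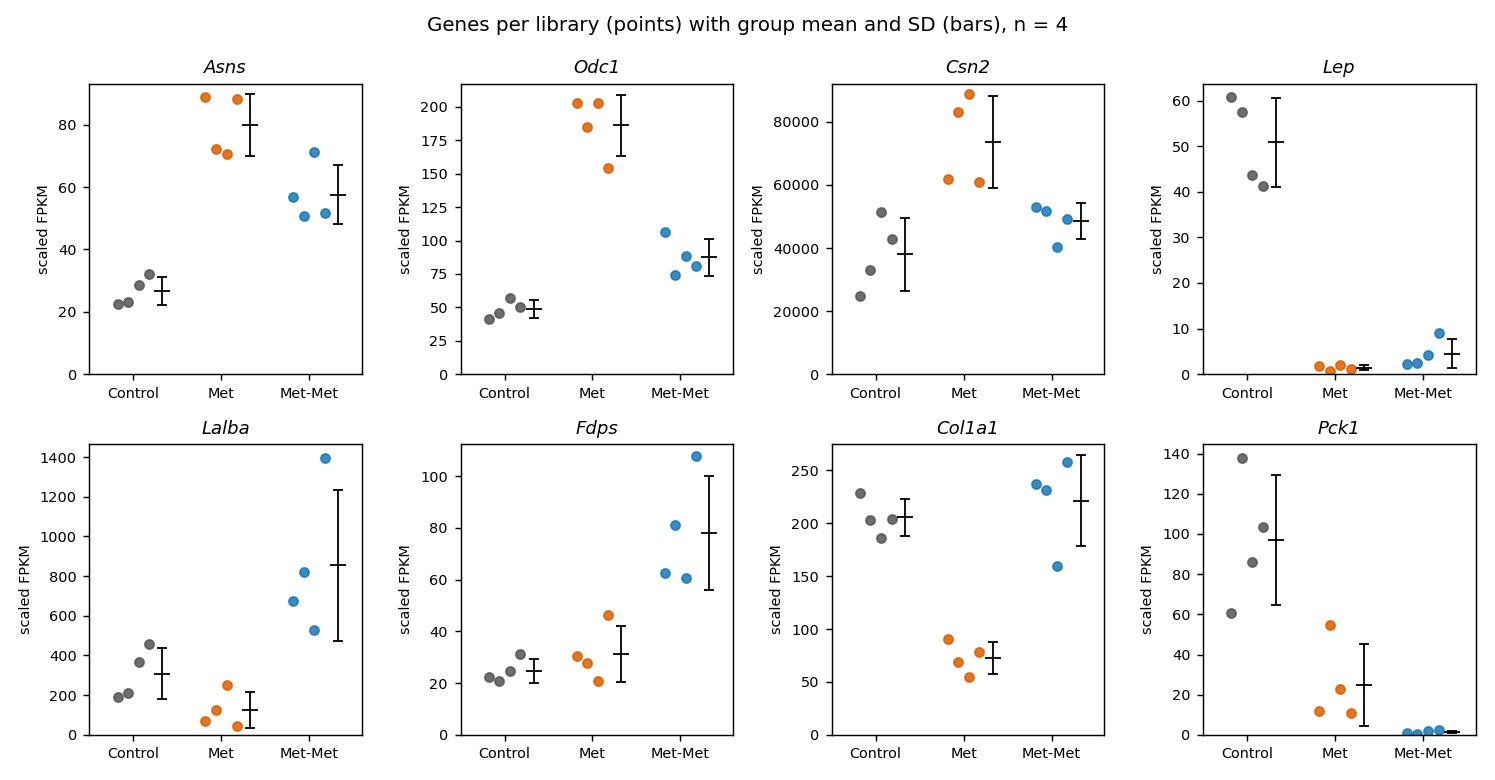
Scaled FPKM of 8 genes in each library (points) of the Control, Met and Met-Met groups, with the mean and SD of 4 libraries (bars). Lep was highest in Control and Col1a1 was lowest in Met (73.0 ± 15.2); Csn2 keeps no difference after quantile normalization.

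In Met-Met glands, cholesterol synthesis genes, ER chaperones and aminoacyl-tRNA synthetases were higher than in Control, and markers of adipocytes and red cells were lower. Adjusted p with an estimated correlation was 0.485 for adipocytes and 0.463 for each other list. Fdps, which makes farnesyl diphosphate on the way to cholesterol, was at 78 ± 22.0 against 24.7 ± 4.63 (1.6, adjusted p = 0.00148). Orm2, an acute phase protein, was at 5.56 ± 2.25 against 0.314 ± 0.0985 (2.26), and Pck1, of glucose and glycerol synthesis, at 1.43 ± 0.725 against 96.9 ± 32.4 (−5.32).

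Limma called 2420 of the 11809 genes, 1250 higher and 1170 lower in Met-Met than in Control, with 73 and 165 at least 2-fold. As deposited the all-gene median was −0.12 and 2082 genes were called, 499 higher and 1583 lower. In the 9 libraries 1844 genes were called, without Control 1 there were 1345, without Control 2 there were 1356, and with library quality weights 4055. The adipocyte marker mean, 6.39 to 6.67 in Control and 4.78 to 6.09 in Met-Met, left 56 calls as a covariate, the B cell marker mean 1466 and both 57. Without the 6 lymphocyte-marked libraries, which leaves 1 Control, 5 genes were called, 3 of them among the 2420. Of the named calls, 53 of 54 were lost there, 42 with the adipocyte covariate or both, and 8 of 62 with the B cell covariate.

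Among the 10 highest fold changes were those of Orm2 (2.26), Krt15 (2.14), Sdf2l1 (1.74), the ribonuclease Rnase1 (1.71), the interferon-induced Oas1a (1.71), Aldh1l2 (1.62), Adm2 (1.61), Fdps (1.6) and the sterol oxidase Msmo1 (1.59). The 10 lowest were Pck1 (−5.32), Sncg (−3.93), Npr3 (−3.63), Hbb-bs (−3.44), Lep (−3.39), Hbb-bt (−3.36), Hba-a1 (−3.05), Hba-a2 (−3.03), Nnat (−2.97) and Plin4 (−2.79). Adm2 was not called without any 1 of the Control libraries (0.0979, 0.0820, 0.0679 and 0.0541 for Control 1 to 4), without Met-Met 1 (0.0752), 2 (0.0697) or 3 (0.0945), or in the 9 libraries (0.0792), range 0.00859 to 0.677.

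The cholesterol synthesis list rose, with a median of 1.15 (1.07 in 9 libraries; adjusted p = 5.12e-11, or 0.463 with an estimated correlation). Of 21 members, 19 rose and 0 fell (19 and 0 over the list alone). They include Dhcr7 (1.31), Nsdhl (1.01) and Mvk (0.91). ER chaperone and unfolded protein response genes rose as a list (median 0.86, 0.86 in 9 libraries, adjusted p = 2.91e-08, or 0.463 with an estimated correlation), as in Pdia6 (1.01) and the calcium-binding chaperone calreticulin, Calr (1.27). Of 18 members, 12 rose and 0 fell (14 and 0 over the list alone). For tRNA synthetases the median was 0.51 (0.54 in 9 libraries; adjusted p = 2.60e-06, or 0.463 with an estimated correlation). Of 20 members, 8 rose and 0 fell (13 and 0 over the list alone), with Nars (0.92) and Lars (0.50), the latter not called as deposited (0.0649, range 9.17e-04 to 0.593). The ATF4 list rose, with a median of 0.45 (0.50 in 9 libraries; adjusted p = 5.50e-06, or 0.485 with an estimated correlation). Of 27 members, 7 rose and 0 fell (7 and 0 over the list alone), among them Asns (57.5 ± 9.42), Atf5 (79.3 ± 21.0) and the leucine transporter Slc7a5 (1.06). Interferon response genes rose (median 0.63, 0.76 in 9 libraries, adjusted p = 2.87e-05, or 0.463 with an estimated correlation), with Bst2 (1.13) and Ifi44 (1.21). Of 15 members, 5 rose and 0 fell (9 and 0 over the list alone). The lactose list rose with a median of 0.54 (0.54 in 9 libraries; adjusted p = 2.13e-04, or 0.463 with an estimated correlation). Of 10 members, 6 rose and 0 fell (7 and 0 over the list alone), including the glucose transporter Slc2a1 (0.95). Erythrocyte genes fell, with a median of −3.05 (−3.18 in 9 libraries; adjusted p = 1.86e-05, or 0.463 with an estimated correlation), Alas2 among them (−1.45). Of 5 members, 0 rose and 5 fell (0 and 5 over the list alone).

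Oxidative phosphorylation genes were higher in Met-Met, with a median of 0.24 (0.30 in 9 libraries), 0.07 quantile-normalized (adjusted p = 1.51e-11, or 0.463 with an estimated correlation). Of 76 members, 24 rose and 0 fell (34 and 0 over the list alone). Members that rose include Atp5g1 (0.99), a subunit of ATP synthase, and Ndufs8 (0.44). Ndufs8 was not called as deposited (0.0559, range 6.03e-04 to 0.396). The list call ended after quantile normalization (adjusted p = 0.0815), range 3.21e-20 to 0.0815. Glutathione and antioxidant genes were called higher (median 0.22, 0.24 in 9 libraries, adjusted p = 0.0165, or 0.463 with an estimated correlation), with Prdx1 (0.59) and the glutathione reductase Gsr (0.61) rising and the catalase Cat (−0.79) falling. Of 22 members, 6 rose and 3 fell (6 and 3 over the list alone). Without Met-Met 4 (adjusted p = 0.0711) and quantile-normalized (0.158) this call was lost, range 8.27e-04 to 0.158. Milk fat genes were called higher as well (median 0.31, 0.32 in 9 libraries, adjusted p = 0.0255, or 0.582 with an estimated correlation), with Acly (1.18), which makes cytosolic acetyl-CoA, and Slc25a1 (1.18), the mitochondrial citrate carrier. Of 23 members, 7 rose and 1 fell (8 and 1 over the list alone). The milk fat call was lost after quantile normalization (0.447), with the B cell covariate (0.196), without Met-Met 4 (0.156) and without the 6 lymphocyte-marked libraries (0.0640), range 2.10e-05 to 0.447.

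Milk protein genes were called higher as a list in Met-Met, with a median of 0.50 (0.44 in 9 libraries; adjusted p = 0.00156, or 0.582 with an estimated correlation). Of 19 members, 3 rose and 0 fell (1 and 0 over the list alone). The butyrophilin gene Btn1a1, of the milk fat globule membrane, was at 611 ± 72.4 against 331 ± 21.0, and Lalba at 854 ± 379.8 against 308 ± 128 (1.47, adjusted p = 0.0481). The list call was lost after quantile normalization (0.0937), with the adipocyte covariate (0.104), the B cell covariate (0.0784) and both (0.404), range 6.06e-06 to 0.404. The Lalba call was lost after quantile normalization (0.0558) and without Control 1 (0.132), Control 2 (0.125), Control 3 (0.0644), Met 1 (0.0559), Met 2 (0.0546), Met-Met 1 (0.0751), Met-Met 2 (0.0915) or Met-Met 4 (0.128), range 0.00678 to 0.502. Milk protein genes took 42.4 ± 4.06% of the summed FPKM in Met-Met, 5.57 percentage points above Control (exact permutation p = 0.229, adjusted p = 0.229 over 3 comparisons), and 4.51 in the 9 libraries (exact permutation p = 0.4). That difference lay between 2.62 and 8.19 percentage points when any 1 library was left out, the lowest without Control 1 and the highest without Control 3.

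Adipocyte markers fell in Met-Met, with a median of −1.07 (−0.89 in 9 libraries; adjusted p = 2.87e-05, or 0.485 with an estimated correlation). Of 15 members, 1 rose and 10 fell (2 and 11 over the list alone), Aqp7 (−1.07) and Adipoq (60.3 ± 32.6 against 169 ± 16.6) among them. With the list's own mean as a covariate the call was lost by construction (0.790, and 0.757 with the B cell mean added, range 6.58e-08 to 0.790). Endothelial markers fell (median −0.35, −0.28 in 9 libraries, adjusted p = 0.00137, or 0.485 with an estimated correlation), with the tight junction gene Cldn5 (−0.97) and the phosphatase Ptprb (−0.48), and their call was lost with the adipocyte covariate (0.179) and with both covariates (0.151), range 5.58e-05 to 0.179. Of 12 members, 0 rose and 5 fell (0 and 6 over the list alone). The B cell and T cell lists were called lower. The B cell median was −1.38 (−1.21 in 9 libraries; adjusted p = 0.00366, or 0.582 with an estimated correlation). Of 10 members, 0 rose and 0 fell (0 and 0 over the list alone). The T cell median was −1.51 (−1.26 in 9 libraries; adjusted p = 0.00111, or 0.582 with an estimated correlation). Of 12 members, 0 rose and 0 fell (0 and 11 over the list alone). Without the 6 lymphocyte-marked libraries both calls were lost, for B cells by construction (0.478 and 0.493), as with the adipocyte covariate (0.104 and 0.0701), the B cell covariate (again by construction, 0.938 and 0.585) and both (0.907 and 0.790), ranges 8.58e-08 to 0.938 and 2.53e-08 to 0.790. The marker means of adipocytes, endothelium and erythrocytes were lower, and that of skin keratinocytes higher, in every Met-Met library than in every Control library (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.107), and the B cell mean gave an exact permutation p of 0.171.

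The ribosomal protein list was not called between Met-Met and Control (median −0.04, 0.02 in the 9 libraries, adjusted p = 0.638; 1 member rose, and 0 over the list alone). Also not called were fibroblasts (median −0.12, 0.0799), cell division (−0.25, 0.325), myoepithelial cells (−0.02, 0.638), macrophages (−0.04, 0.195), prolactin and STAT5 genes (−0.11, 0.638) and brown adipocytes (0.40, 0.740). Lower calls appeared for cell division without Met-Met 3 (3.04e-04) or the 6 lymphocyte-marked libraries (0.0103), for fibroblasts without Control 3 (0.0370) or Met-Met 4 (0.00665) and quantile-normalized (0.00129), and for ribosomal proteins quantile-normalized (3.22e-05) or without those 6 (0.0418). With both covariates cell division was called higher (0.00673). The methionine cycle list (0.19, 0.0953, but called higher as deposited, 0.0354, and unfiltered, 0.00841) included Odc1 (0.84), and the transporter list (0.07, −0.04 as deposited, 0.289) included the glutamine carrier Slc1a5 (−1.02). Peptide transport and hydrolysis (0.16, 0.161), skeletal muscle (0.10, 0.963), skin keratinocytes (0.65, 0.111, but called higher as deposited, 0.00965) and luminal epithelium (0.05, −0.08 as deposited and −0.10 quantile-normalized, 0.370) were not called. Signs differed within the uncalled lists of plasma cells (median 0.16, mean −0.04, 0.655), Schwann cells (median −0.04, mean 0.02, 0.06 quantile-normalized, 0.889), PI3K, AKT and mTORC1 genes (median −0.02, test positive, 0.638), hormone-sensing cells (median −0.12, 0.05 quantile-normalized, 0.621), DNA and RNA methylation (median 0.04, −0.07 as deposited, test negative, 0.963) and the immediate-early list (median −0.06, 0.00 quantile-normalized, 0.668).

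Of the genes followed throughout, Asns (1.09, adjusted p = 7.62e-04) and Elf5 (0.49, 0.00963) rose and Adipoq fell (−1.63, 0.00467). Prlr rose (0.37, 0.0356). The Elf5 call was lost as deposited (0.0697) and quantile-normalized (0.0568), range 0.00178 to 0.445. The Prlr call was lost with both scalings (0.0755 and 0.0727), in the 9 libraries (0.117) and without Control 1 (0.101), Control 2 (0.0985), Met-Met 1 (0.0881) or Met-Met 2 (0.0891), range 0.00446 to 0.947. Csn2 (0.40, 0.246), Wap (0.50, 0.385), Stat5a (−0.01, 0.958), Mat2a (−0.24, 0.697), Slc15a2 (0.16, 0.717), Mtor (0.06, 0.535, and −0.05 as deposited) and Krt14 (0.19, 0.235) were not called. Mki67 (−0.42, 0.146) was called only without Met-Met 3 (−0.61, adjusted p = 0.0278). The receptors Ghr (−0.93) and Erbb4 (−0.92) fell.

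The fold changes of Met and Met-Met against the same Control libraries correlated across genes at r = 0.679, genes not being independent replicates. Unchanged groups simulated against these controls gave 0.498 on average and 0.560 at most over 100 simulations, and 6 splits of the Control libraries, which use separate controls for each comparison, gave 0.495 to 0.574. The covariance was 0.126 against 0.0189 simulated, a difference of 0.107, and 0.0992 to 0.113 with split controls. Both comparisons called 631 genes higher and 762 lower, where independent lists would share 166 and 176, and 17 in opposite directions.

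**Figure D2:**
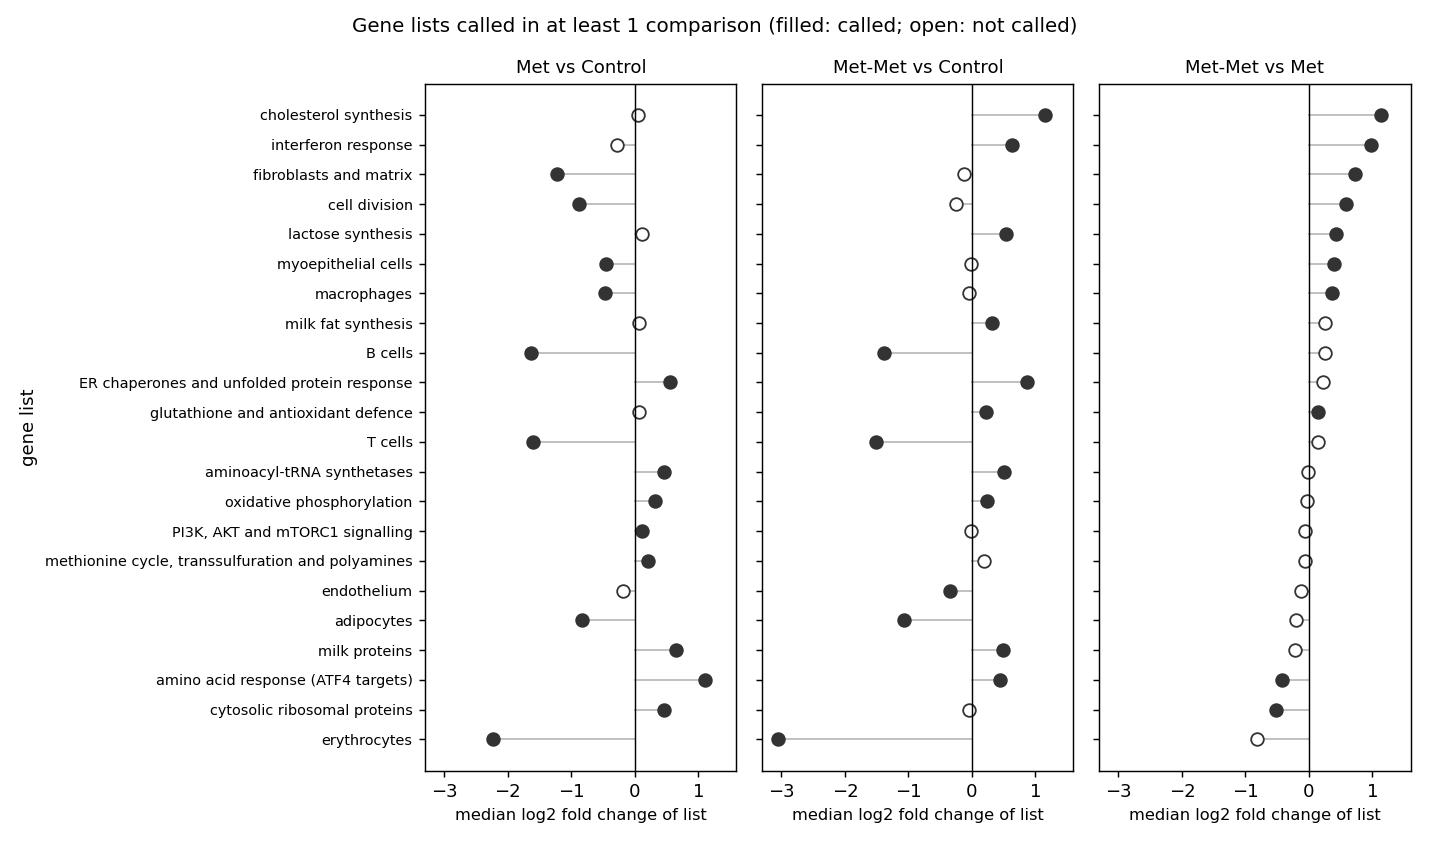
Median log2 fold change of each gene list called in at least 1 of the 3 comparisons (filled circles, called at the preset correlation; open circles, not called). Cholesterol synthesis stands at 0.05, 1.15 and 1.14 and ribosomal proteins at 0.46, −0.04 and −0.52 in the 3 panels; with FPKM as deposited the medians of the methionine cycle and the mTORC1 list between Met and Control turn negative, as do those of 4 uncalled lists there, and 5 uncalled lists between Met-Met and Met turn positive.

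Replacing part of the injected methionine with the dipeptide went with higher levels of cholesterol synthesis, matrix and interferon response genes and of Lalba, and with lower levels of ribosomal protein genes. The 4 lists gave adjusted p of 0.321 or 0.366 with an estimated correlation and 0.0810 by exact permutation of list means (0.243 for ATF4). Lalba was at 854 ± 379.8 in Met-Met and 123 ± 90.4 in Met (2.97, adjusted p = 0.00406). Col1a1, a chain of type I collagen, was at 222 ± 42.6 and 73.0 ± 15.2 (1.59).

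Limma called 1397 of the 11809 genes between Met-Met and Met, 697 higher and 700 lower in Met-Met, with 86 and 83 at least 2-fold. As deposited the all-gene median was 0.15 and 1830 genes were called, 1556 higher and 274 lower. In the 9 libraries 917 genes were called, 720 of them among the 1397, and without the 6 lymphocyte-marked libraries 484, with 383 shared and 21 of 61 named calls lost. Only the 8 libraries of the 2 groups gave 751 calls and library quality weights 2096. Leaving out 1 library gave 826 calls without Met 1, 913 without Met 2, 792 without Met 3, 2316 without Met 4 and 675 without Met-Met 4. In the 9 libraries 17 of the 68 named calls were lost, among them Saa1 (0.0615), Cox7a2l (0.0555), Txnip (0.0935), Asns (0.18), Krt14 (0.0973), Lao1 (0.0570), Lpl (0.0567), Cd36 (0.0943), Mrc1 (0.0535), Ddit4 (0.0652), Trib3 (0.114), Tk1 (0.0672), Dnmt1 (0.0656), Oas1a (0.0747) and Oas2 (0.0501).

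Among the 10 highest fold changes were those of the serum amyloid genes Saa2 (4.64) and Saa1 (3.55), Lalba (2.97), Orm2 (2.49), the sterol regulator Insig1 (2.22), the acute phase gene Lrg1 (2.19), the retinoic acid carrier Crabp2 (1.6), Col1a1 (1.59) and Clca3a2 (1.53). Saa2 was at 190.3 ± 211 against 4.54 ± 2.91 and Saa1 at 144 ± 137 against 9.26 ± 6.70, and reads of these near-identical genes could be split between them. The 10 lowest were Cox7a2l (−4.94), Pck1 (−3.17), the chemokine Ccl28 (−2.19), Tfcp2l1 (−2.15), the corticosteroid-induced kinase Sgk1 (−2.06), Plpp4 (−1.96), the thioredoxin inhibitor Txnip (−1.92), Retsat (−1.88), Fhad1 (−1.86) and the glucocorticoid-induced Fkbp5 (−1.84). Cox7a2l was at 73.5 to 87.2 in the Met libraries and at 73.9 in Control 3, and at 0.806 to 2.07 in the other 7, so its reads could be assigned elsewhere in some libraries, which was not tested. Crabp2 was not called without Met 2 (0.0676), Met 3 (0.0776), Met-Met 3 (0.0559) or Met-Met 4 (0.0809). Txnip was not called without Met 1 (0.0670), Met 2 (0.0758), Met 3 (0.0763), Met-Met 2 (0.0606), Met-Met 3 (0.0717) or Met-Met 4 (0.0767), and Fhad1 without Met 1 (0.0514) or Met-Met 4 (0.0586). Over alternatives these ranged from 0.00337 to 0.0809, 0.00852 to 0.0935 and 0.00259 to 0.0586.

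Ribosomal protein genes were lower in Met-Met than in Met, with a median of −0.52 (−0.60 in 9 libraries), −0.34 as deposited and −0.28 quantile-normalized (adjusted p = 1.31e-26, or 0.321 with an estimated correlation). Of 77 members, 0 rose and 51 fell (0 and 62 over the list alone). Their share of the summed FPKM was 6.20 ± 0.785% against 7.28 ± 0.778% (exact permutation p = 0.0857). Rpl23 was at 293 ± 16.3 in Met-Met, 440.0 ± 36.4 in Met (−0.58) and 294 ± 13.7 in Control. Cholesterol synthesis genes were higher (median 1.14, 1.15 in 9 libraries, adjusted p = 3.01e-12, or 0.366 with an estimated correlation), with Nsdhl (1.22), Hmgcs1 (1.13) and Fdps at 78 ± 22.0 against 31.3 ± 10.8. Of 21 members, 15 rose and 0 fell (18 and 0 over the list alone). Cell division genes rose as a list, with a median of 0.58 (0.69 in 9 libraries; adjusted p = 1.59e-10, or 0.515 with an estimated correlation). Of 30 members, 11 rose and 0 fell (20 and 0 over the list alone), for example Tk1 (0.71), Cdk1 (0.96) and Rrm2 (1.09). Fibroblast and matrix markers rose (median 0.73, 0.69 in 9 libraries, adjusted p = 9.35e-09, or 0.321 with an estimated correlation), with Col1a2 (1.41), Col5a1 (1.24) and Fbn1 (1.03). Of 14 members, 9 rose and 0 fell (10 and 1 over the list alone). Interferon response genes also rose, with a median of 0.97 (1.06 in 9 libraries; adjusted p = 1.11e-07, or 0.366 with an estimated correlation). Of 15 members, 8 rose and 0 fell (12 and 0 over the list alone), with Oas1a (1.23) and Oas2 (1.06).

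The ATF4 target list was lower in Met-Met than in Met, with a median of −0.43 (−0.43 in 9 libraries; adjusted p = 5.48e-06, or 0.515 with an estimated correlation). Of 27 members, 0 rose and 8 fell (0 and 10 over the list alone). Those that fell include Cebpg (−0.78), Eif4ebp1 (−0.84), Trib3 (−1.50) and Ddit4 (−1.06). Myoepithelial markers rose (median 0.39, 0.41 in 9 libraries, adjusted p = 9.83e-05, or 0.321 with an estimated correlation), with Acta2 (0.93) and Tagln (0.68) higher and the basal transcription factor Trp63 (−0.49) lower, and Trp63 was not called as deposited (0.0668, range 0.00478 to 0.550). Of 12 members, 5 rose and 1 fell (8 and 1 over the list alone). The lactose list rose with a median of 0.43 (0.52 in 9 libraries; adjusted p = 5.19e-04, or 0.321 with an estimated correlation). Of 10 members, 4 rose and 0 fell (5 and 0 over the list alone), with the sugar enzymes Hk1 (0.82) and Pgm2 (0.50) beside Lalba.

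Glutathione and antioxidant genes were called higher at the edge of the threshold (median 0.15, 0.16 in 9 libraries, adjusted p = 0.0496, or 0.515 with an estimated correlation), with Prdx1 (0.53) and Txn1 (0.43). Of 22 members, 5 rose and 0 fell (6 and 0 over the list alone). Macrophage markers were likewise called higher (median 0.36, 0.37 in 9 libraries, adjusted p = 0.0496, or 0.515 with an estimated correlation), with the mannose receptor Mrc1 (0.72) rising and the kinase Mertk (−0.67) falling. Of 11 members, 5 rose and 1 fell (7 and 1 over the list alone). The glutathione call was lost without Control 1 (0.0542), Control 2 (0.0557), Control 4 (0.0571), Met 1 (0.0792), Met 4 (0.0855), Met-Met 3 (0.0554) or Met-Met 4 (0.127), without the 6 lymphocyte-marked libraries (0.0759) and with high Gm26917 as a covariate (0.0831), range 0.0166 to 0.127. The macrophage call was lost in the 9 libraries (0.0851), as deposited (0.0757), with the B cell covariate (0.108), both covariates (0.126) or high Gm26917 as a covariate (0.0648), without the 6 lymphocyte-marked libraries (0.0960), and without Control 1 (0.0542), Control 2 (0.0557), Control 4 (0.0572), Met 1 (0.0654), Met 4 (0.0855), Met-Met 1 (0.0666) or Met-Met 4 (0.0643), range 0.00468 to 0.126. The marker means of myoepithelial cells, fibroblasts and macrophages were higher in every Met-Met library than in every Met library (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.143).

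**Figure D3:**
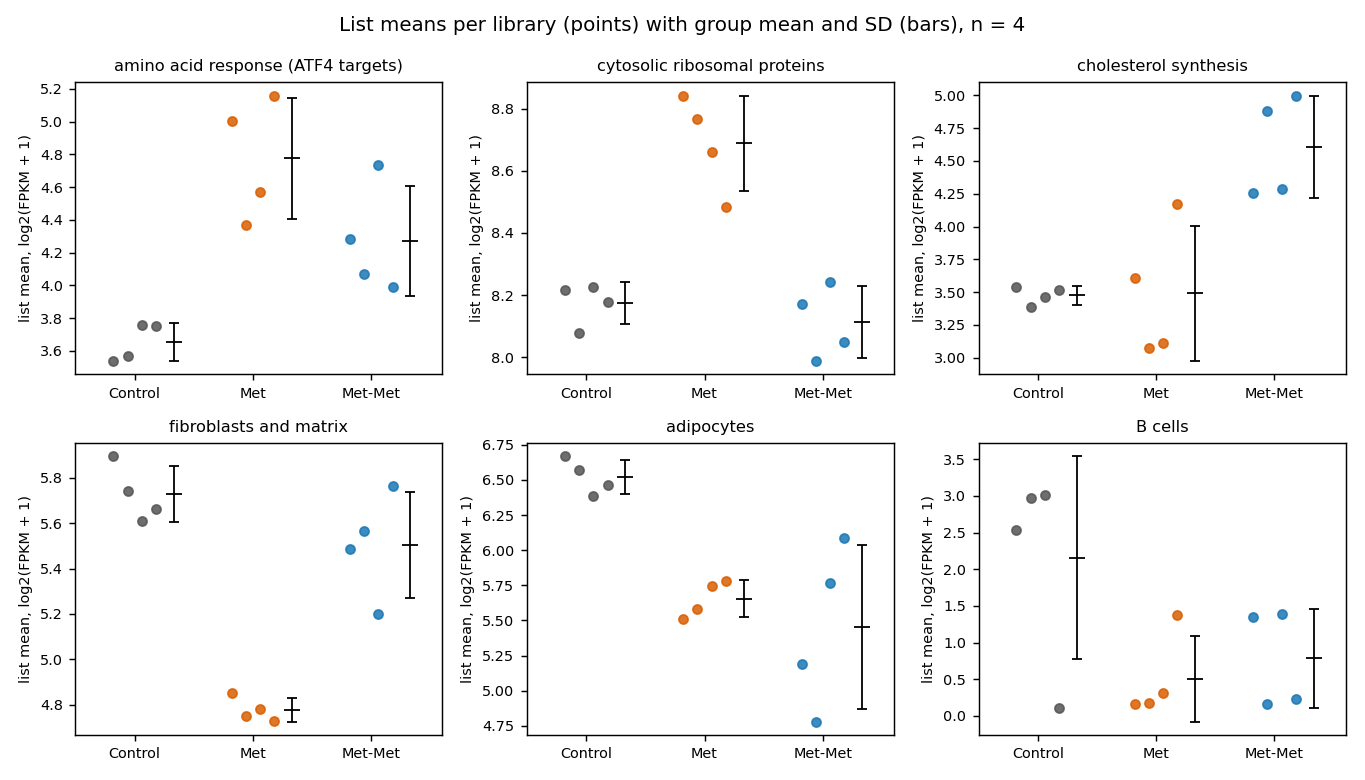
Mean log2(FPKM + 1) of 6 gene lists in each library (points) by group, with the mean and SD of 4 libraries (bars). Ribosomal protein genes were higher in each Met library than in any other library, and the B cell markers split the libraries within each group, from 0.108 to 3.01 in Control.

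The methionine and dipeptide groups were not told apart in several lists. For list means, the range that an exact permutation test at 0.05 does not exclude was −0.83 to 0.77 around 0.09 for milk proteins, −0.14 to 0.80 around 0.25 for milk fat, −0.34 to 0.15 around −0.07 for oxidative phosphorylation, −0.40 to 0.54 around 0.03 for tRNA synthetases, −0.42 to 0.60 around 0.21 for ER chaperones and −1 to 0.58 around −0.20 for adipocytes, all on the log2 scale as Met-Met minus Met. It included 0 for the called ATF4 list (−1.17 to 0.37). It left out 0 for 3 lists that camera did not call, peptide transport and hydrolysis (0.09 to 0.23 around 0.14), prolactin and STAT5 (−0.27 to −0.03 around −0.14) and PI3K, AKT and mTORC1 (−0.29 to −0.01 around −0.12). There exact permutation gave p = 0.0286, the smallest possible (adjusted p = 0.0810 over 34 lists), and fry adjusted p = 0.0440, 0.0433 and 0.0440. For the milk protein share it was −15.1 to 1.03 percentage points around −5.44 (exact permutation p = 0.114, adjusted p = 0.171 over 3 comparisons, −5.84 and p = 0.2 in the 9 libraries).

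None of those lists but ATF4 was called by camera between Met-Met and Met with all 12 libraries, scaled values and no covariate. Without Met-Met 4 oxidative phosphorylation (0.00519, and 0.00371 with high Gm26917 as a covariate) and adipocytes (0.0157) were called lower, and without Met 4 ER chaperones were called higher (3.74e-04). The milk protein list had a median of −0.23, a mean of 0.09 and a median of 0.07 quantile-normalized (adjusted p = 0.742), with Lao1 lower (−0.76) and Btn1a1 and Lalba higher (Btn1a1 0.47). Milk fat genes had a median of 0.26 (adjusted p = 0.529). Of 23 members, 3 rose and 3 fell (7 and 5 over the list alone). Acly (0.85) rose while the lipoprotein lipase Lpl (−0.48) and the fatty acid carrier Cd36 (−0.62) fell. Lpl (0.142) and Cd36 (0.0640) were not called after quantile normalization, ranges 0.00788 to 0.142 and 0.00656 to 0.143. Prolactin and STAT5 genes (median −0.02, 0.15 as deposited and 0.00 quantile-normalized, adjusted p = 0.273) included Ghr (−1.11) and Socs2 (−1.05), which fell. In the methionine cycle list (median −0.06, 0.08 as deposited, 0.346) Odc1 fell from 186 ± 22.9 to 87.5 ± 13.8 (−1.08), and 1 member rose, with the same counts of 1 and 1 over the list alone. The aminopeptidase Anpep (1.32) rose in the peptide list (median 0.15, 0.176), the transporter subunit Slc7a7 (−1.07) fell in the transporter list (median −0.08, 0.08 as deposited, 0.736), and in the methylation list (median −0.05, 0.11 as deposited, 0.529) Wtap (−0.66) fell and Dnmt1 (0.45) rose.

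Nor were the remaining lists called in that fit. Skeletal muscle genes had a median of −1.03 (adjusted p = 0.0688), and in the 9 libraries −2.13 (0.00232). They were called as deposited (1.35e-04) and without Met 1 (0.0106), Met 3 (0.0125), Met 4 (0.0345) or Met-Met 4 (0.0397). Erythrocytes (0.00519, and 0.00338 as deposited) and endothelium (0.0166) were called lower without Met-Met 4, and luminal epithelium higher without Met 2 (0.0244) or Met 3 (0.0255). ER chaperones had a median of 0.23 (0.0993) and were called higher in the 9 libraries (0.35, 6.63e-04), quantile-normalized (0.0490) and without the 6 lymphocyte-marked libraries (0.00197). Medians and adjusted p were −0.81 and 0.0942 for erythrocytes, −0.20 and 0.349 for adipocytes (0.12 in the 9 libraries), 0.11 and 0.1 for luminal epithelium, 0.14 and 0.742 for T cells, 0.25 and 0.529 for B cells, 0.05 and 0.427 for Schwann cells, and 0.10 and 0.887 for the immediate-early list. The sign of the median turned as deposited for PI3K, AKT and mTORC1 genes (−0.06 to 0.09, adjusted p = 0.0993), oxidative phosphorylation (−0.03 to 0.14, 0.190), endothelium (−0.12 to 0.05, 0.176), hormone-sensing cells (−0.04 to 0.08, 0.529), plasma cells (−0.08 to 0.05, 0.948), brown adipocytes (−0.08 to 0.07, 0.841), skin keratinocytes (−0.09 to 0.04, test positive, 0.473) and tRNA synthetases (−0.01 to 0.17, mean 0.03, 0.968).

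Of the genes followed throughout, Krt14, a basal keratin, rose from 23.2 ± 2.34 to 33.0 ± 2.72 (0.49, adjusted p = 0.0143) and Asns fell from 79.9 ± 9.88 to 57.5 ± 9.42 (−0.47, 0.0488). The Asns call was lost in 22 of 30 alternatives (range 0.0241 to 0.223), including FPKM as deposited (0.223) and each fit without 1 library (0.0534 to 0.125) except those without Control 4 and Met-Met 3. Not called were Csn2 (−0.59, 95% interval −1.10 to −0.07), Wap (−0.76, −1.59 to 0.08), Elf5 (0.30, 0.06 to 0.53), Stat5a (0.10, −0.14 to 0.34), Prlr (0.01, −0.23 to 0.25), Slc15a2 (0.15, −0.45 to 0.75), Mtor (0.09, −0.05 to 0.24), Mki67 (0.54, 0.11 to 0.96) and Adipoq (−0.55, −1.23 to 0.12). Elf5 was called as deposited (0.0291), quantile-normalized (0.0289) and with high Gm26917 as a covariate (0.0468), and Adipoq with the adipocyte covariate (0.0471). These limma intervals are not adjusted for the number of genes. Mat2a (−1.12, −1.95 to −0.28, adjusted p = 0.0787) was called only without Met 2 (−1.52, adjusted p = 0.0158) and with library quality weights (0.0215).

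Genes called higher in Met than in Control were mostly lower again in Met-Met than in Met where both comparisons called them. There were 398 such genes, against 93.1 for independent lists, and 353 with the opposite pattern (105 for independent lists), while 9 were called higher and 11 lower in both steps. Both steps share the Met libraries, which pulls their fold changes apart by chance. The correlation across genes was −0.525 where simulation with no effect gave −0.499. With the Met libraries split, so that the steps share none, it was −0.435 to −0.189, and the simulated value is no reference for that. The covariance was −0.0838 against −0.0190 simulated, and −0.0748 to −0.0397 with the Met libraries split.

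Among long noncoding RNAs, Pinc, an RNA known from the pregnant mammary gland, was at 5.33 ± 1.36 in Met-Met, 0.659 ± 0.385 in Met and 0.975 ± 0.536 in Control. It was called against Met (2.35, adjusted p = 4.77e-04) and against Control (2.01, 0.00153). Gm12863, annotated antisense to another gene, was at 30.3 ± 12.1 in Met and 6.34 ± 1.00 in Control (2.08), and the strand of the libraries is not given in the sources used here, so reads of an antisense RNA and its partner could be mixed. Of 873 annotated lncRNAs tested, 74 were called in Met against Control (31 higher and 43 lower), 35 in Met-Met against Control (9 and 26) and 43 in Met-Met against Met (10 and 33). Of 397 assembled lncRNAs without annotation, 27 (21 and 6), 8 (1 and 7) and 10 (0 and 10) were called, and the last comparison had 75 at an unadjusted p under 0.05. Between Met-Met and Met, Gm42793 (2.29) and C530043A13Rik (1.70) rose and E230001N04Rik (−1.68), AC160765.1 (−1.72) and AC160121.1 (−1.90) fell. Gm42793 (0.0640) and C530043A13Rik (0.0832) were not called in the 9 libraries, ranges 0.00187 to 0.0640 and 0.00187 to 0.0832. AC160121.1 (2.14) and AC160765.1 (1.91) rose and 2610016A17Rik (−1.27), AC158595.1 (−1.27) and Gm36840 (−1.67) fell in Met against Control. Without Control 2 the AC158595.1 call was lost (0.0579, range 0.00347 to 0.118). In Met-Met against Control AC133947.2 (1.90) and C530043A13Rik (1.51) rose, and 2610016A17Rik (−1.20), Gm36840 (−1.37) and AW112010 (−1.23) fell.

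AW112010 was not called without any 1 library except Control 4 (0.0552 to 0.131), nor in the 9 libraries (0.0739), range 0.00352 to 0.204. For Met-Met against Control, 2610016A17Rik was lost without Control 1 (0.0535, range 0.00629 to 0.0660) and C530043A13Rik without Met-Met 1 (0.0532) or Met-Met 4 (0.0556, range 0.00315 to 0.0708). The 74 annotated calls of Met against Control became 34, 21 and 46 without Control 1, 2 and 3, 37, 48 and 27 without Met 1, 2 and 3, 30 with the B cell covariate and 145 as deposited. The 35 of Met-Met against Control became 11, 19 and 18 without Control 1, 2 and 3, 14, 99, 20 and 11 without Met-Met 1 to 4, 80 in the 9 libraries and 71 as deposited. The 43 of Met-Met against Met became 21, 26 and 21 without Met 1, 2 and 3, 22 and 14 without Met-Met 3 and 4, 18 in the 9 libraries and 23 as deposited.

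Assembled lncRNAs carry only the identifiers of the deposited table. XLOC_076804 rose from 0.372 ± 0.148 in Control to 3.28 ± 1.14 in Met (2.09, adjusted p = 8.19e-05), while XLOC_050428 fell from 1.88 ± 0.377 to 0.131 ± 0.0906 in Met (−1.91) and to 0.0982 ± 0.115 in Met-Met (−2). XLOC_090451 fell from 1.6 ± 0.222 in Met to 0.207 ± 0.0913 in Met-Met (−1.58, adjusted p = 1.13e-04). The 27 calls of Met against Control became 15 without Control 1, 10 with the B cell covariate and 52 at a mean of at least 0.1 FPKM. The 8 of Met-Met against Control became 5, 4 and 5 without Control 1, 2 and 3, 5 without Met-Met 2, 3 in the 9 libraries, 3 with the B cell covariate and 1 at a mean of at least 0.1 FPKM. The 10 of Met-Met against Met became 4, 3 and 23 without Met 2, 3 and 4, 5, 3, 3 and 2 without Met-Met 1 to 4, 6 in the 9 libraries and 5 as deposited.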

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

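The tests of the weighed patterns (lymphocyte, ribosomal and cholesterol genes) were chosen only after the result was seen, while the splits of the libraries were planned.

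In a group of 4 libraries, 1 lay far from the other 3 when its gap to the nearest took up most of the group's range, and the share of the range is given for each case. Among library summaries and list means this held for 8 of 111 groups, where chance gives about 1 in 20, or 5.6. Control 4 was low for T cell (0.958) and B cell (0.833) markers, and Met 4 high for both (0.869 and 0.877). Skeletal muscle markers were high in Met 2 (0.987) and in Met-Met 4 (0.875), and skin keratinocyte markers in Met 2 (0.846). The methionine cycle list was high in Control 3 (0.852).

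Among named genes it held for 23 of 429 groups, against 21.5 by chance. In Control these were Atp2b2 (0.887) and Mki67 (0.878), low in Control 1, and Calr (0.845), Cox7a2l (0.988) and Nnat (0.987), the last low and the others high in Control 3. In Met they were Cd22 (0.962), Fcer2a (0.928), Chac1 (0.894), Ddit4 (0.886) and Cish (0.920), the last low and the others high in Met 4. Oas2 was high in Met 3 (0.846), Plpp4 low (0.889) and Wtap high (0.975) in Met 1, and Slc7a5 low in Met 2 (0.866). In Met-Met 3, Atf5 (0.855), Cth (0.834), Mthfd2 (0.835), Slc1a5 (0.920) and Trib3 (0.889) were high and Ramp3 (0.853) low. Erbb4 was high in Met-Met 2 (0.860), Gnmt in Met-Met 4 (0.928) and Slc7a7 in Met-Met 1 (0.913).

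B and T cell markers stood higher in 3 of 4 Control libraries than in all 8 treated ones. Lymph node tissue in some glands is consistent with the stromal genes of lymph nodes, since the 6 libraries highest for Ccl21a, Ccl19, Cxcl13, Madcam1 and Chst4 were the 6 highest for B cells (6 of 6, 3 by chance). Ccl21a had been seen before the test, and without it the remaining 4 genes gave the same 6 libraries. Members differ: Ccl19 was listed at 0 in Met-Met 1 and 3, and Madcam1 was lowest in Control 1 (0.795) and highest in Met 2 (4.94). Fewer lymphocytes under either treatment cannot be told apart from chance (exact permutation p = 0.143, Met against Control), since Control 4 breaks the pattern (B cell mean 0.108).

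Ribosomal protein mRNAs were lower in Met-Met than in Met. A trend of short mRNAs, such as RNA quality, stays open, as mRNA lengths were not measured. The ribosomal change lay −0.51 on the log2 scale from that of oxidative phosphorylation genes (exact permutation p = 0.0286). High Gm26917 (median −0.60 without those 3 libraries) and muscle and skin RNA in Met 2 (−0.46 without it) are argued against as whole causes. An effect of the dipeptide stays open as a hypothesis found and tested on the same data.

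Cholesterol synthesis genes were higher in Met-Met than in Met. Adipocyte means hardly differed (−0.20), so their covariate (median 1.14) cannot decide. Argued against as whole causes are the 3 libraries with high Gm26917 (1.15 without them) and any 1 library (at least 1.03, without Met 2). A dipeptide response stays a hypothesis. Food intake and dissection time were not tested.

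Each comparison was repeated for all 35 splits of its 8 libraries. The gene counts of Met-Met against Met (1397, at most 3 in another split), Met against Control (3346, at most 776) and Met-Met against Control (2420, at most 182) were reached by 1 of 35 splits, the real one, so chance can be excluded. The split with 776 put Met 4 with Control 1, 2 and 3, and that with 182 Met-Met 1, joining libraries with lymphocyte markers. The same holds for annotated lncRNAs (43, 74 and 35 calls in the order above, at most 1, 16 and 6 elsewhere) and for assembled ones (10, 27 and 8, at most 5, 4 and 0), each reached by 1 split. For gene lists the real split led only between Met and Control (16 lists, at most 15 elsewhere), at the preset correlation. Other settings called 12 to 17 lists and an estimated correlation 0. Chance stays open for Met-Met and Met (10 lists, 19 splits with as many, at most 16). So it does for Met-Met and Control (15, 5 and 17).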

How the results depend on the processing

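The fits and counts without the 3 libraries with high Gm26917 or the 6 with lymphocyte markers, without genes listed at 0, with an indicator of high Gm26917, with both covariates and with the B cell covariate for lncRNAs were chosen only after the result was seen. Where no cause is named below, the cause was not tested.

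Genes called between Met-Met and Met (1397) became 751 with the 8 libraries alone and 484 without the 6 libraries, both with fewer samples, 2096 with library quality weights, 917 without the 3 libraries, and 675 to 2316 without 1 library. With the replicate block there were 841, and the numbers do not pair the samples. Met against Control (3346) gave 2192 at a mean of at least 5 FPKM, with fewer genes tested, 394 with the adipocyte covariate, 1478 with the B cell covariate, 133 with both, 8 without the 6 libraries and 2126 to 3570 without 1 library. Met-Met against Control (2420) gave 4055 with weights, 56, 1466 and 57 with the same covariates, 5 without the 6 libraries and 1345 to 2751 without 1 library. The adipocyte mean separates Control from both treated groups, so as a covariate it removes most of their difference by construction. Leaving out the 6 libraries leaves 1 Control.

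With an estimated correlation camera called 0, 0 and 0 lists in the 3 comparisons, where the preset one called 10 (Met-Met against Met), 16 (Met against Control) and 15 (Met-Met against Control). In the same order fry called 11, 14 and 13, and leaving out 1 library gave 8 to 13, 14 to 17 and 14 to 16. The replicate block ended the calls of the mTORC1 list between Met and Control (0.0625) and of glutathione genes and macrophages between Met-Met and Met (0.0566 each). Between Met and Control, calls came as deposited for amino acid transporters (0.00798), milk fat (0.0213) and muscle (5.72e-06), and without the 6 libraries for cholesterol (0.0229, lower), endothelium (0.0400, lower) and plasma cells (0.0116). Milk fat was also called with the adipocyte (5.04e-04) and both covariates (0.0101), and endothelium and plasma cells with the B cell covariate (0.0481 each). Met-Met against Control gained plasma cells without the 6 libraries (0.00533). The milk protein share differed by −6.54 to −3.48, 8.06 to 13.6 and 2.62 to 8.19 percentage points without 1 library, and passed the threshold only without Control 3, at 13.6. The correlation of the 2 comparisons with Control was 0.623 (without Met 4) to 0.741 (without Control 4).

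Annotated lncRNAs between Met-Met and Met (43) became 23 as deposited, 21 with the replicate block, 18 without the 3 libraries and 14 to 48 without 1 library. Met against Control (74) gave 145 as deposited, 35 with the block, 30 with the B cell covariate and 21 to 93 without 1 library. Met-Met against Control (35) gave 71 as deposited, 14 with the block, 80 without the 3 libraries and 11 to 99 without 1 library. Assembled lncRNAs between Met-Met and Met (10) became 5 as deposited, 6 with the block, 6 without the 3 libraries and 2 to 23 without 1 library. Met against Control (27) gave 52 at a mean of at least 0.1 FPKM, 10 with the B cell covariate and 15 to 38 without 1 library. Met-Met against Control (8) gave 1 at a mean of at least 0.1, 4 with the block, 3 without the 3 libraries, 3 with the B cell covariate and 4 to 9 without 1 library.

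Some named genes changed direction, most of them near 0. Met against Control, Elf5 was −0.11 as deposited and −0.12 after quantile normalization. Slc15a2 was −0.28 and −0.0407 there, −0.23 with the adipocyte covariate, −0.44 with the B cell covariate, −0.59 with both, −0.16 with a single transcript, −0.39 without the 6 libraries and −0.21 to 0.24 without 1 library. Adipoq was 0.13 with the adipocyte covariate and 0.12 with both. Without the 6 libraries Fcer2a was 0.11 and Cd22 0.0643. Mtor was −0.0676 to 0.00414 without 1 library. In Met-Met against Control, Slc15a2 was −0.14, −0.22 and −0.41 with the adipocyte, B cell and both covariates, −0.00708 with a single transcript, −0.60 without the 6 libraries and −0.00395 to 0.37 without 1 library. Wap was −0.0099 with the adipocyte covariate and −0.21 with both, Mki67 0.0163 with both and Mat2a 0.19 without the 6 libraries. Mtor was −0.0541 as deposited and −0.0138 with both, and Stat5a 0.0403 with weights and −0.0769 to 0.083 without 1 library. In Met-Met against Met, Slc15a2 was −0.0581 with weights, −0.21 without the 6 libraries and −0.0829 to 0.37 without 1 library. Prlr was −0.0372, −0.0289 and −0.0102 with the adipocyte covariate, a single transcript and both covariates, −0.0105 without the 3 libraries and −0.0289 to 0.0466 without 1 library.

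Of the values of named genes under alternatives, 6028 kept their direction and their side of the threshold, 537 kept the direction and lost the call, 16 kept the direction and gained a call, and 44 turned. Depth is unknown, so what it limits was not measured.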

Other observations

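The test of glucocorticoid-induced genes was chosen before its result was seen, and the genes with levels of 2 kinds were looked for after the values were seen.

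Fkbp5 and Sgk1, both induced by glucocorticoids, were higher in Met than in the other groups (Sgk1 53.3 ± 5.37 against 16.4 ± 1.04 in Control and 12.4 ± 3.60 in Met-Met). The hypothesis of a glucocorticoid response in Met was tested on 14 other genes induced by these hormones. Their mean was 0.61 higher in Met than in Control on the log2 scale (exact two-sided permutation p = 0.0857) and differed by −1.005 between Met-Met and Met (exact permutation p = 0.0571), neither past the threshold. The mean was 5.42, 5.78 and 5.57 in Met 1 to 3, above all Control (4.45 to 4.96) and Met-Met libraries (4.18 to 4.53), and 4.51 in Met 4, so the response cannot be told apart from the spread between 4 libraries. Of the 14 genes, 7 rose and 0 fell in Met against Control, and 0 rose and 8 fell in Met-Met against Met.

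Some genes had levels of 2 kinds that did not follow the groups alone. As with Rpl12, Hsp90aa1 was at 129, 267 and 186 in Met 3, Met 4 and Met-Met 2 and at 1.65 to 3.64 in the others. Rpl26 was at 398 and 441 in Control 1 and 3 and at 11.9 to 27.2 in the others. Cox7a2l was high in the Met libraries and Control 3 only.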
